A study of Rattus norvegicus with 13 samples.

How the data were processed

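Per the labels' protocols, paired kidneys were taken from rats, one kidney was perfused with iron oxide particles while the renal artery of the other was clamped, and glomeruli of the perfused kidney were isolated by sieving and magnet to a purity over 99% by phase contrast microscopy. For the other groups the protocols describe laser capture microdissection of frozen sections of 10 µm, with about 800 glomerular cross-sections named also for the samples titled LCM 20, and 2 rounds of RNA amplification. Biotin-labelled cRNA was made from 6 µg of total RNA for the sieved samples, per the labels' protocols. What the title number 20 stands for is not stated, the replicate numbers are not said to mark the rat, the extraction text also mentions anti-Thy1.1 rats although every sample is given as untreated, and the sample description speaks of embryos, which does not match the other fields. The group names used here are sieved (titled iron), LCM800 and LCM20.

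The deposited values are linear array signals in intensity units, made with MAS5 per the submitters' processing notes, with 1 column per sample for 13 samples and 15923 probe sets. The mean of each array after 2% of the values at each end are left out lay between 498 and 501, so each array had been scaled and no further normalization between arrays was applied. Values were taken as log2(signal + 65.29), where the pseudocount is the 20th percentile of all signals, so that changes of dim genes are smaller than the ratio of their signals. The 57 control probe sets and the lowest 30% of probe sets by mean log2 over all samples were left out, which left 11106. Gene symbols came from the probe gene table and the gene reference given with the data: 12783 probe sets had exactly 1 symbol, 312 had several and 2771 had none. No probe set positions were used. A gene was represented by its probe set with 1 symbol and the highest mean log2 over all samples, which gave 8081 genes.

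Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with an intensity trend), with the 3 groups in 1 fit and no covariate, as each group has only 4 or 5 arrays, and Benjamini-Hochberg adjustment at 0.05 over all probe sets tested. Lists were tested with limma's camera at its preset correlation of 0.01 between genes, adjusted over 20 lists of at least 5 measured genes, and again with an estimated correlation. The 20 lists were podocyte, mesangial, glomerular endothelial, parietal epithelial, vascular smooth muscle and juxtaglomerular, proximal tubule, loop, distal tubule and collecting duct, leukocyte, erythrocyte and platelet, immediate early and stress, heat shock, inflammatory cytokine, hypoxia and glycolysis, iron and oxidative stress, ribosomal protein, oxidative phosphorylation, extracellular matrix, complement and coagulation, cell cycle, and interferon response genes. They were written from general knowledge, without a check that their genes are confined to the cell type named, and a gene in 2 lists, such as Vegfa, counts in both. Genes named in the text follow a rule that takes, per comparison, the 6 largest rises and 6 largest falls among genes past the test with sample ranges that do not overlap (symbols starting with LOC or RGD left out), the 2 largest changes past the test in each list, and 17 genes fixed beforehand, of which 2 are not reported here; some of the largest changes are given as a range over several genes, and not every fixed gene is printed for LCM20 against LCM800. Other list members are named after their values were seen, to give the exceptions in a list or where 5 or fewer genes moved. The groups, the tests, the lists, the naming rule and most alternatives were fixed before the data were examined.

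Agreement between arrays is Pearson's r over tested probe sets, for which genes are not independent replicates. The spread of an array is its root mean square deviation from its group mean, scaled for group size. Spread and the 3′ minus 5′ log2 signals of β-actin, Gapdh and hexokinase controls were compared by exact two-sided permutation tests, adjusted over 3 and 9 tests. The correlation of the 2 comparisons against sieved was set beside 100 simulations of unchanged groups that share the sieved arrays, and beside splits of the sieved arrays into 2 and 2. Random lists, 10000 for each list, were matched on mean log2 over all arrays in 20 bins, with seed 20240501. For the proximal tubule, cell cycle and interferon lists only, 10000 random lists were also matched on mean log2 in the sieved arrays. For the spread of the proximal tubule list over the sieved arrays this was repeated with each sieved array left out, after the values were seen.

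Alternatives fixed beforehand were quantile normalization, equal medians, no pseudocount (values under 1 set to 1), 4 times the pseudocount, no filter, the lowest 60% left out, no intensity trend, array weights, the replicate number as a block, only the 2 groups compared, 1 probe set per gene, the mean of all probe sets of a gene, a fold of at least 2, an estimated correlation, and each array left out in turn. Chosen after seeing the data were leaving out LCM800 replicates 4 and 5 or replicates 1, 2 and 3, and the mean level of 18 spike-in control probe sets as a covariate. The 3′ minus 5′ value of β-actin served as a covariate for 1 test only. The fit was tested on simulated data with 200 changed of 11106 probe sets per comparison. Of 2-fold changes 45%, 42% and 45% were recovered for LCM800 against sieved, LCM20 against sieved and LCM20 against LCM800, of 4-fold changes 92%, 93% and 91%, and false calls made up 8.05%, 4.26% and 4.23% of calls. Of 50 simulated lists over 8081 genes 5 were shifted, and the list test recovered 5 of these with 0 false calls among the others. Genes were simulated as independent, so this does not show how often the list test calls falsely where genes vary together. The estimated correlation was 0.537 for the proximal tubule list.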

Results

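Gene expression was measured on 13 one-colour rat arrays with RNA from kidney glomeruli of untreated rats aged 18 weeks. Glomeruli are the capillary tufts that filter blood into the nephron. Per the labels' protocols, one kidney of each pair was perfused with iron oxide and its glomeruli were isolated by magnet and sieve, giving the sieved group (n = 4). Glomeruli of the opposite kidney were cut out of frozen sections by laser capture microdissection, and their RNA went through 2 rounds of amplification. These samples form the groups titled LCM800 (n = 5) and LCM20 (n = 4), where only the titles tell what sets them apart. The median signal per array ran from 237 to 321 intensity units, and the number of arrays limits the precision of every value. Changes below are differences of mean log2(signal + 65.3), given ± SE of the fit, and adjusted p values are two-sided and come from limma. A list test compares a list of genes with all other genes, and none of its calls held with an estimated correlation between the genes of a list.

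The comparison of LCM800 with sieved glomeruli asks how far amplified RNA from microdissected glomeruli gives the profile of glomeruli isolated in bulk. Proximal tubule genes were the group that differed most. Of 34 such genes 31 fell and 2 rose, the same counts as adjusted over the list alone, with a median change of −2.98 (quartiles −3.57 and −1.95; list test adjusted p = 4.05e-17; adjusted p = 0.346 with an estimated correlation). The mean log2 of the list was 12.20 ± 0.48 (SD, n = 4) in sieved arrays and 9.63 ± 0.25 (SD, n = 5) in LCM800 arrays. Ass1, which makes argininosuccinate, fell by 4.41 ± 0.31 (n = 5 and 4; adjusted p = 9.30e-08), from a mean signal of 5906 to 193. Fxyd2, a subunit of the sodium pump, fell by 4.14 ± 0.38 (n = 5 and 4; adjusted p = 7.87e-07). The phosphate transporter gene Slc34a1 fell by 1.82 ± 0.33 (n = 5 and 4; adjusted p = 0.000351). Pck1 and Cyp2d4 were the exceptions and rose by 1.07 and 0.71. Sieved replicate 3 had the lowest list mean of its group, 11.49, against 12.34 to 12.50 in the other sieved arrays.

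Genes of the loop of Henle, distal tubule and collecting duct fell as a list too, with a median of −0.90 (list test adjusted p = 0.000356; adjusted p = 0.363 with an estimated correlation). Of 21 genes 10 fell and 1 rose, over all genes and adjusted over the list alone. This list was not set beside random lists matched on sieved level. Klk1, tissue kallikrein, fell by 3.72 ± 0.31 (n = 5 and 4; adjusted p = 3.31e-07), and Umod, which encodes uromodulin, fell by 2.56 ± 0.42 (n = 5 and 4; adjusted p = 0.000154). Spp1, which encodes osteopontin, fell by 3.06 ± 0.24 (n = 5 and 4; adjusted p = 2.49e-07). The single gene that rose was the collecting duct water channel gene Aqp2, by 1.32 ± 0.41 (n = 5 and 4; adjusted p = 0.0131). Without sieved replicate 3 the Aqp2 change was 0.98 and no longer passed (adjusted p = 0.0533), within adjusted p values of 0.00162 to 0.185 over its alternatives.

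Podocyte genes moved in both directions. Of 18 genes 5 rose, 8 fell and 5 did not pass, with the same counts adjusted over the list alone, a median of 0.25 and a list test in the opposite direction (adjusted p = 0.707). The median change over all tested probe sets was 0.22 in this comparison, so a list median near it is not a rise relative to other genes. Synpo, which encodes the actin-associated podocyte protein synaptopodin, rose by 1.71 ± 0.27 (n = 5 and 4; adjusted p = 9.37e-05), from 12.58 ± 0.54 to 14.29 ± 0.26 (mean log2 ± SD). Rhpn1 rose by 2.68 ± 0.44 (n = 5 and 4; adjusted p = 0.000156), and Nphs1, the gene of the slit diaphragm protein nephrin, rose by 1.19 ± 0.37 (n = 5 and 4; adjusted p = 0.0126). The other, dimmer probe sets of Synpo and Nphs1 did not rise, with changes of −0.46 (adjusted p = 0.084) and −0.65 (adjusted p = 0.0538) that did not pass. Mme, which encodes the peptidase neprilysin, fell by 2.31 ± 0.37 (n = 5 and 4; adjusted p = 0.000105), and Ptpro, Actn4 and Vegfa fell, with changes of −1.43, −1.14 and −1.03. Whether genes that fell in this and the other glomerular lists are confined to glomerular cells was not tested, so a fall need not be a loss of glomerular RNA. Podxl, the podocalyxin gene, fell by 0.72 ± 0.25 (n = 5 and 4; adjusted p = 0.0234). This was the smallest fall among its 3 tested probe sets, whose changes ran from −1.47 to −0.72. The Podxl call ended without sieved replicate 1 (adjusted p = 0.0552) or sieved replicate 3 (adjusted p = 0.0847), and that of Nphs1 without sieved replicate 4 (adjusted p = 0.0558). Podxl also did not pass with the replicate number as a block, at −0.69 (adjusted p = 0.0675), or with quantile normalization, at −0.58 (adjusted p = 0.102). Over the alternatives the adjusted p ran from 0.00995 to 0.102 for Podxl and from 7.00e-05 to 0.12 for Nphs1. For the transcription factor gene Wt1 the probe set with the highest signal changed by 0.47 ± 0.34 without passing (adjusted p = 0.263), while its other probe set fell by 1.44 (adjusted p = 0.000439). Without sieved replicate 3 the first of these passed at 0.84 (adjusted p = 0.0279, the lowest of its alternatives, which ran up to 0.596).

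Glomerular endothelial genes had a median of 0.85, and their list test did not pass (adjusted p = 0.322). Of 16 genes 7 rose and 2 fell, against 8 and 2 adjusted over the list alone. Egfl7, a vascular guidance factor gene, rose by 2.27 ± 0.29 (n = 5 and 4; adjusted p = 1.75e-05), Rasip1 by 2.23 ± 0.39 (adjusted p = 0.000228) and the receptor gene Kdr by 1.24 ± 0.36 (adjusted p = 0.00924). Vwf, the von Willebrand factor gene, fell by 1.31, and Pecam1 changed by 0.25 (adjusted p = 0.559). With array weights Pecam1 passed at 0.71 (adjusted p = 0.00875, the lowest of its alternatives, which ran up to 0.847). The list means were 9.55 ± 0.55 (SD, n = 4) in sieved and 10.18 ± 0.29 (SD, n = 5) in LCM800 arrays, and sieved replicate 3 had 10.36 against 9.12 to 9.44 in the other sieved arrays. Without sieved replicate 3 the list's median was 1.28 and its test passed (adjusted p = 0.0466, the lowest of its alternatives, which ran up to 0.835).

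Mesangial genes had a median of 0.39 (list test adjusted p = 0.849), with 6 higher and 3 lower of 18 genes, and 7 and 3 adjusted over the list alone. Nt5e, which encodes an ectonucleotidase, fell by 2.32 ± 0.29 (n = 5 and 4; adjusted p = 1.24e-05) and Igfbp5 fell by 1.57 ± 0.22 (adjusted p = 3.86e-05), while Cspg4 and Itga8 rose by 1.52 and 1.07. The other Igfbp5 probe set changed by 0.41 without passing. Thy1, the target of the antibody in the anti-Thy1.1 model, rose by 1.38 ± 0.44 (adjusted p = 0.0152), a call that ended without sieved replicate 2 (adjusted p = 0.0692, in a range of 0.000418 to 0.141 over its alternatives). The other Thy1 probe set changed by 0.27. Pdgfrb changed by −0.31 (adjusted p = 0.383). Parietal epithelial genes, those of the cells lining Bowman's capsule, had a median of −0.94 (list test adjusted p = 0.0787), with 2 higher and 5 lower of 9 and 3 and 5 adjusted over the list alone. With no filter that test passed (adjusted p = 0.0377, the lowest of its alternatives, which ran up to 0.346). In that list Cd24 fell by 3.26 ± 0.27 (n = 5 and 4; adjusted p = 3.30e-07) and Prom1 fell by 1.69 ± 0.28 (adjusted p = 0.000153). Among 8 vascular smooth muscle and juxtaglomerular cell genes, with a median of 0.28 (list test adjusted p = 0.8), 3 were higher and 1 lower, also adjusted over the list alone. Tpm2 rose by 2.26 ± 0.55 (adjusted p = 0.00289) and Akr1b7 fell by 2.65 ± 0.75 (adjusted p = 0.00774). Tpm2 was at 1.37 and did not pass without LCM800 replicates 1, 2 and 3 (adjusted p = 0.104, in a range from 2.71e-06 over its alternatives).

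**Figure D1:**
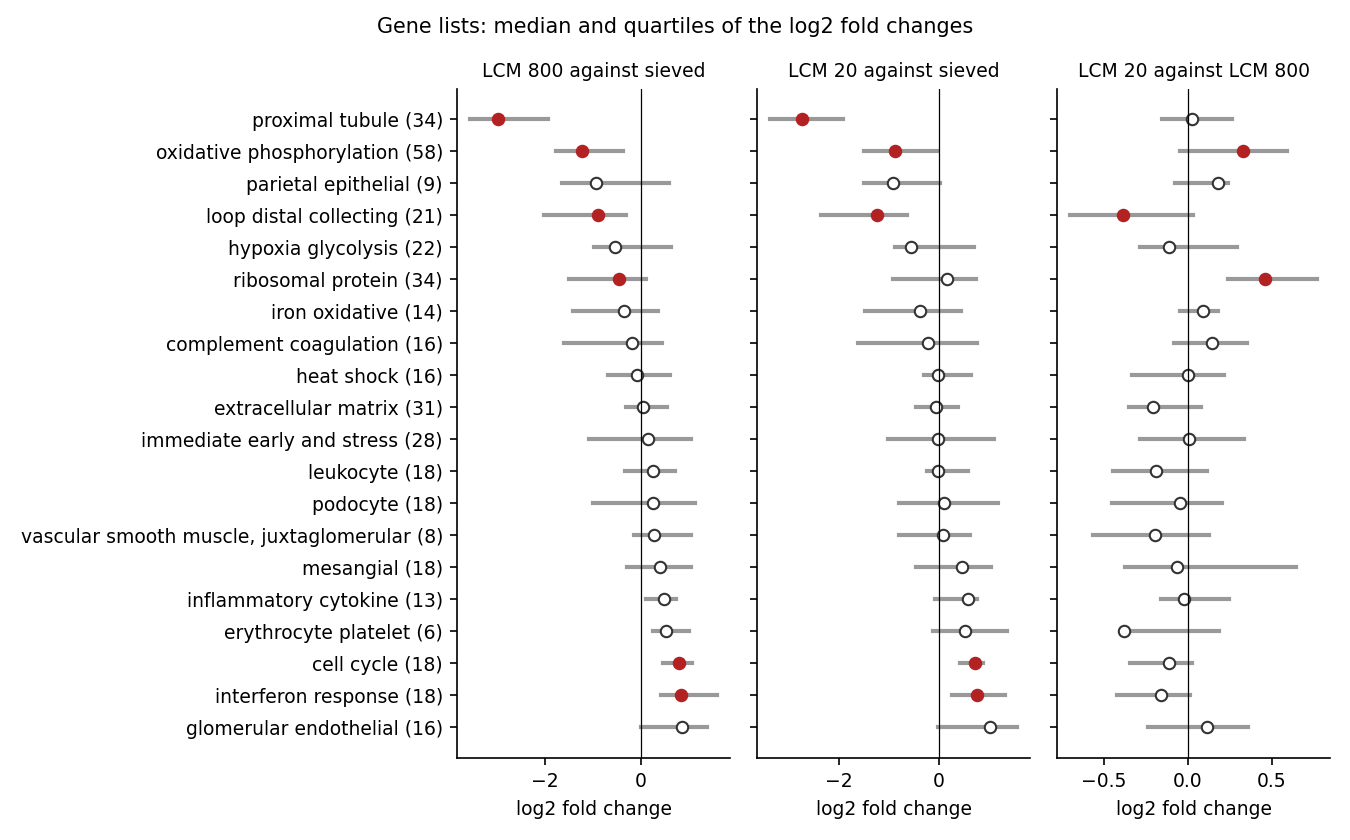
Median log2 change of each of the 20 gene lists (x axis) in the 3 comparisons, with bars from the lower to the upper quartile over the list's genes and the number of genes in brackets. Filled red points mark lists past the list test at adjusted p 0.05, and the proximal tubule median is −2.98 in LCM800 and −2.75 in LCM20 against sieved.

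Oxidative phosphorylation genes were lower in LCM800, with 35 of 58 lower and 6 higher, the same counts as adjusted over the list alone. Their median was −1.24 (list test adjusted p = 9.66e-10; adjusted p = 0.144 with an estimated correlation). Atp5mg, which encodes a subunit of the mitochondrial ATP synthase, fell by 5.06 ± 0.23 (n = 5 and 4; adjusted p = 2.62e-09), from a mean signal of 3261 to 35.7, which lies under the pseudocount, and Uqcrfs1 fell by 3.49 ± 0.52 (adjusted p = 6.14e-05). Ndufb3, of respiratory complex I, went the other way and rose by 1.84. Ribosomal protein genes had a median of −0.46 (list test adjusted p = 0.00109; adjusted p = 0.348 with an estimated correlation), with 5 higher and 15 lower of 34, and 6 and 15 adjusted over the list alone. Rplp0 fell by 2.98 ± 0.42 (n = 5 and 4; adjusted p = 3.84e-05) and Rps24 fell by 2.73 ± 0.22 (adjusted p = 2.66e-07), while Rpl13a rose by 2.21. Random lists matched on mean log2 over all arrays had medians of 0.29 and 0.32, but neither list was matched on sieved level. Both are bright in sieved arrays, at means of 11.50 and 12.01. Lists matched to the proximal tubule list (sieved mean 12.20) on sieved level had a median of −1.24. A general fall of genes bright in sieved arrays was therefore not separated from these falls. On the same arrays the β-actin control signal at the 3′ end exceeded that at the 5′ end by 2.77 ± 1.03 in LCM800 and 0.55 ± 0.02 in sieved samples (SD, n = 5 and 4; exact two-sided permutation p = 0.0159). Sieved replicate 3, the lowest sieved array for proximal tubule genes, was also the lowest for oxidative phosphorylation genes, with a list mean of 11.34 against 11.48 to 11.61.

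Cell cycle genes were higher in LCM800, with 12 of 18 higher and none lower, also adjusted over the list alone, and a median of 0.79 (list test adjusted p = 0.0103; adjusted p = 0.346 with an estimated correlation). Mcm7 and Mcm4, which encode parts of the replicative helicase, rose by 1.35 ± 0.33 (n = 5 and 4; adjusted p = 0.00291) and 1.25 ± 0.25 (adjusted p = 0.000665). Without LCM800 replicates 1, 2 and 3 the list's median was 0.61 (adjusted p = 0.0564, in a range of 0.00613 to 0.346 over its alternatives) and Mcm7 was at 0.59 (adjusted p = 0.111, in a range from 1.98e-06), and neither passed. Interferon response genes had a median of 0.84 (list test adjusted p = 0.00932; adjusted p = 0.348 with an estimated correlation), with 11 of 18 higher and 1, B2m with a change of −1.80, lower, also adjusted over the list alone. The transcription factor gene Stat2 had the largest rise of the comparison, 4.34 ± 0.47 (n = 5 and 4; adjusted p = 3.89e-06), from a mean signal of 131 to 3947. Its other probe set changed by 1.40. Usp18, which is induced by interferon, rose by 2.26 ± 0.24 (adjusted p = 3.73e-06). Random lists matched on their level in the sieved arrays also rose, by a median of 0.66 for lists like the cell cycle list and 0.49 for lists like the interferon list. Matched on mean log2 over all arrays, they had medians of 0.27 and 0.25.

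Leukocyte genes had a median of 0.24 and a mean of −0.08 with a list test upwards (adjusted p = 0.995), 7 of 18 being higher and 4 lower, also adjusted over the list alone. The 4 lower genes all serve antigen presentation by major histocompatibility complex class II, a grouping made after their values were seen and not tested as a list. RT1-Ba fell by 3.33 ± 0.36 (n = 5 and 4; adjusted p = 3.73e-06), RT1-Bb fell by 2.62 ± 0.29 (adjusted p = 4.28e-06), Cd74 fell by 1.85 ± 0.47 (adjusted p = 0.00403) and RT1-Da fell by 1.44 ± 0.31 (adjusted p = 0.00122). For RT1-Ba and RT1-Bb another probe set of the gene rose, by 1.30 each. Laptm5 and the T cell gene Cd3d rose by 1.71 and 1.32. Of 6 erythrocyte and platelet genes, with a median of 0.53 (list test adjusted p = 0.596), 3 were higher and 1 lower, also adjusted over the list alone. Alas2, of haem synthesis in red cells, rose by 2.42 ± 0.37 (adjusted p = 7.09e-05) from a signal of 40.7, under the pseudocount, Slc4a1 fell by 1.43 ± 0.36 (adjusted p = 0.00374), and the globin gene Hbb changed by 0.49 (adjusted p = 0.505).

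None of the handling and stress lists passed the list test in LCM800. The 28 immediate early and stress genes had a median of 0.15 and a mean of −0.02 with a list test downwards (adjusted p = 0.707), with 11 higher and 10 lower, and 12 and 10 adjusted over the list alone. Atf3 rose by 2.11 ± 0.31 (n = 5 and 4; adjusted p = 5.81e-05), from a signal of 33.5 under the pseudocount, and Egr1 by 0.78 ± 0.23 (adjusted p = 0.00973), Gadd45a fell by 2.65 ± 0.28 (adjusted p = 2.96e-06), and Fos changed by 0.30 (adjusted p = 0.51). Without LCM800 replicates 1, 2 and 3 Fos passed at 1.09 (adjusted p = 0.0236, the lowest of its alternatives, which ran up to 0.93). Among 16 heat shock genes 5 were higher and 4 lower, also adjusted over the list alone, with a median of −0.10 (list test adjusted p = 0.596). Hsp90ab1 fell by 2.79 ± 0.46 (adjusted p = 0.000143) and Hspb1 rose by 2.06 ± 0.70 (adjusted p = 0.0221). The Hspb1 call ended without sieved replicate 1 (adjusted p = 0.0569) or 2 (0.0672) or LCM800 replicate 2 (0.0513) or 3 (0.0591), and Hspb1 was at 0.40 without LCM800 replicates 1, 2 and 3 (adjusted p = 0.633, in a range from 1.12e-05). Of 13 inflammatory cytokine genes 5 were higher and none lower, also adjusted over the list alone, with a median of 0.48 (list test adjusted p = 0.37), and Il1b rose by 1.18 ± 0.22 (adjusted p = 0.000413) and Csf1 by 1.24 ± 0.25 (adjusted p = 0.000686). Hypoxia and glycolysis genes had 6 higher and 10 lower of 22, also adjusted over the list alone, and a median of −0.54 (list test adjusted p = 0.0994). That test passed with no filter (adjusted p = 0.044), with the lowest 60% of probe sets left out (adjusted p = 0.0496) and without LCM800 replicates 4 and 5 (adjusted p = 0.0446), in a range up to 0.438. Eno1 fell by 3.61 ± 0.31 (adjusted p = 4.46e-07) and Gpi fell by 2.30 ± 0.34 (adjusted p = 5.17e-05). Iron and oxidative stress genes had 3 higher and 6 lower of 14, and 4 and 6 adjusted over the list alone, with a median of −0.37 (list test adjusted p = 0.0994). Without sieved replicate 3 that median was −0.56 and the test passed (adjusted p = 0.0466, in a range of 0.0226 to 0.505 over its alternatives). It also passed with the lowest 60% of probe sets left out, at a median of −1.36 (adjusted p = 0.0245), with no filter (adjusted p = 0.0226) and with array weights (adjusted p = 0.0446). In the iron list Gclc fell by 3.92 ± 0.42 (adjusted p = 3.71e-06), Sod2 fell by 2.58 ± 0.35 (adjusted p = 2.73e-05) and the haem oxygenase gene Hmox1 rose by 1.02 ± 0.22 (adjusted p = 0.00123).

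Over all 11106 probe sets tested, 5764 (51.9%) differed between LCM800 and sieved glomeruli, 3533 being higher and 2231 lower. With the medians of the arrays set equal 5612 passed, 3195 higher and 2417 lower. At a fold of at least 2 there were 3223, 1688 higher and 1535 lower, and 4752 probe sets (42.8%, against 1.59% by chance) had sample ranges that did not overlap. The other genes with the largest rises were Inf2, Lcmt1, Mad1l1, Rc3h1 and Coro1c, between 3.15 ± 0.22 for Coro1c and 3.81 ± 0.69 for Inf2 (n = 5 and 4). Those with the largest falls were Ly6i, Slco1a6, Mif, Gpx4 and Xpnpep2, between −5.15 ± 0.47 for Ly6i and −4.47 ± 0.33 for Xpnpep2. Mif, a cytokine gene, had a mean signal of 2808 in sieved and 51.6 in LCM800 arrays. The LCM800 signals of Mif, Slco1a6 and Xpnpep2 lie under the pseudocount, which therefore helps set the size and order of these falls.

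LCM20 against sieved glomeruli addresses the same question for the microdissected samples with the other number in their titles. Proximal tubule genes were again the group furthest apart, with 31 of 34 lower and none higher, also adjusted over the list alone, and a median of −2.75 (list test adjusted p = 9.73e-18; adjusted p = 0.383 with an estimated correlation). Ass1 fell by 4.13 ± 0.33 (n = 4 and 4; adjusted p = 4.51e-07), Fxyd2 fell by 4.12 ± 0.40 (adjusted p = 1.69e-06) and Slc34a1 fell by 2.98 ± 0.35 (adjusted p = 1.10e-05). Genes of the loop of Henle, distal tubule and collecting duct had a median of −1.25 (list test adjusted p = 7.32e-07; adjusted p = 0.383 with an estimated correlation), with 15 of 21 lower and none higher, also adjusted over the list alone. Klk1 fell by 3.55 ± 0.32 (n = 4 and 4; adjusted p = 1.04e-06) and Umod fell by 3.13 ± 0.45 (adjusted p = 5.78e-05), and Aqp2 changed by −0.33 (adjusted p = 0.557). The list means of LCM20 were 9.67 ± 0.60 for proximal tubule and 8.84 ± 0.36 for the more distal segments (SD, n = 4), against 12.20 ± 0.48 and 10.38 ± 0.55 in sieved arrays. In sieved replicate 3 these means were the lowest of the group, 11.49 and 9.56.

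**Figure D2:**
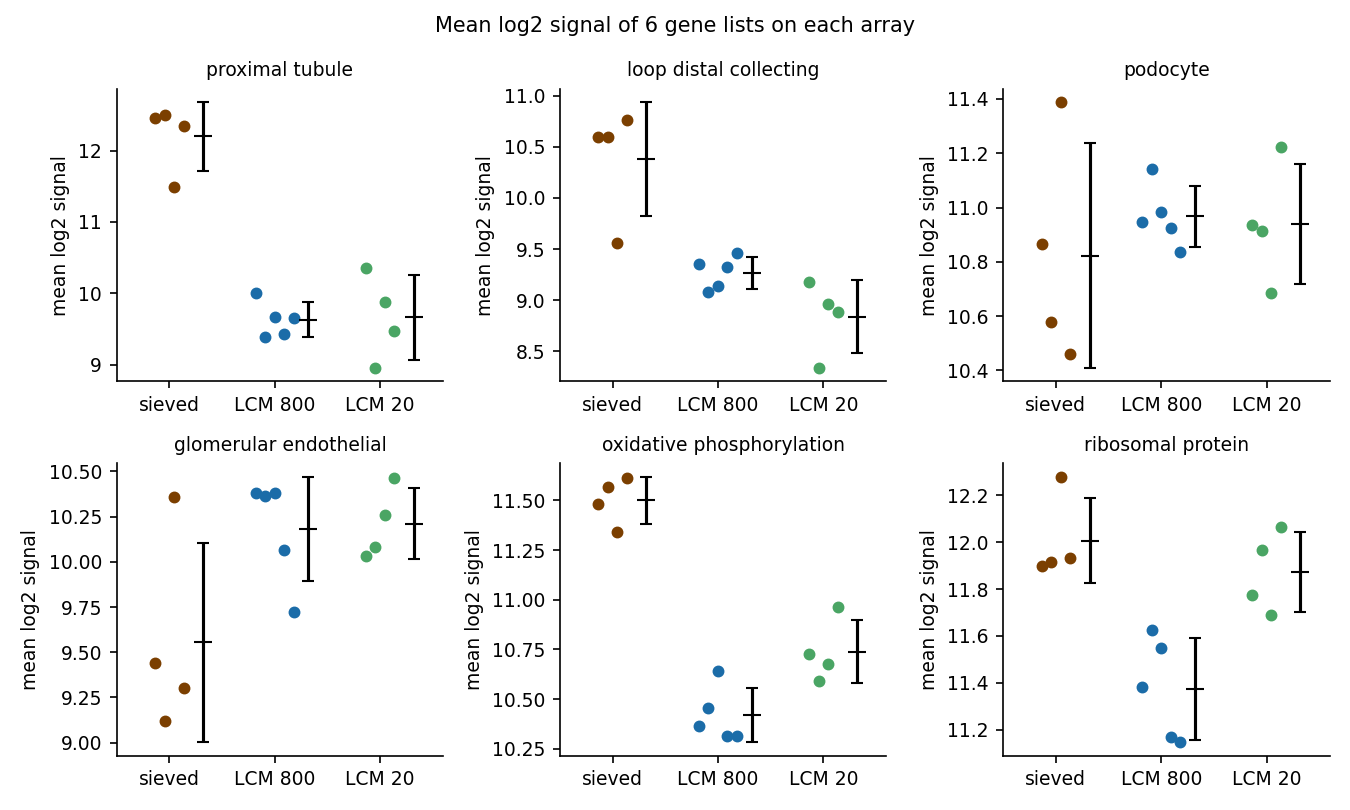
Mean log2(signal + 65.3) of 6 gene lists (y axis) on each array, by group, where points are arrays and bars show the mean ± SD. Sieved replicate 3 has the lowest proximal tubule mean of its group, 11.49, and the highest podocyte mean, 11.39.

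Podocyte genes moved in both directions in LCM20 too, with 6 higher, 5 lower and 7 not past the test, and 6 and 5 adjusted over the list alone. Their median was 0.10, against 0.17 over all tested probe sets in this comparison, and the list test pointed down (adjusted p = 0.752). Synpo rose by 1.59 ± 0.28 (n = 4 and 4; adjusted p = 0.00035), Rhpn1 by 2.16 ± 0.47 (adjusted p = 0.00164) and Nphs1 by 1.30 ± 0.38 (adjusted p = 0.0123), while Mme fell by 2.28 ± 0.39 (adjusted p = 0.000239). The other probe sets of Synpo and Nphs1 changed by −0.53 (adjusted p = 0.0665) and −0.48 (adjusted p = 0.178). Podxl changed by −0.60 ± 0.26 without passing (adjusted p = 0.0728), although it passed at −0.75 without sieved replicate 4 (adjusted p = 0.0454, in a range up to 0.224 over its alternatives). Changes of its 3 tested probe sets ran from −1.33 to −0.60. Wt1 changed by 0.20 (adjusted p = 0.672) with its other probe set lower at −1.38 (adjusted p = 0.00109). Glomerular endothelial genes had 8 higher and 2 lower of 16, also adjusted over the list alone, and a median of 1.02 (list test adjusted p = 0.21). Egfl7 rose by 2.07 ± 0.31 (n = 4 and 4; adjusted p = 8.32e-05), Kdr by 1.97 ± 0.38 (adjusted p = 0.000636) and Emcn by 1.32, Plvap and Vwf fell, Plvap by a log2 change of −1.88, and Pecam1 changed by 0.09 (adjusted p = 0.858). Without sieved replicate 3 the endothelial median was 1.40 and the list test passed (adjusted p = 0.0337, the lowest of its alternatives, which ran up to 0.788).

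Mesangial genes in LCM20 had 7 higher and 2 lower of 18, also adjusted over the list alone, and a median of 0.47 (list test adjusted p = 0.752). Both subunit genes of soluble guanylate cyclase had a probe set that rose, Gucy1a1 by 2.34 ± 0.44 (n = 4 and 4; adjusted p = 0.000581) and Gucy1b1 by 2.29, and Nt5e fell by 2.33 ± 0.30 (adjusted p = 2.73e-05). The other Gucy1a1 probe set changed by −0.25 without passing. Thy1 changed by 0.64 (adjusted p = 0.268) and Pdgfrb by −0.55 (adjusted p = 0.157). Without sieved replicate 3 Thy1 passed at 1.11 (adjusted p = 0.0354, the lowest of its alternatives, which ran up to 0.699). Parietal epithelial genes had 2 higher and 5 lower of 9, also adjusted over the list alone, and a median of −0.92 (list test adjusted p = 0.145). With no filter that test passed (adjusted p = 0.0489, the lowest of its alternatives, which ran up to 0.383). Cd24 fell by 3.08 ± 0.28 (n = 4 and 4; adjusted p = 1.06e-06) and Pax8 fell by 1.67 ± 0.40 (adjusted p = 0.00315). The 8 vascular smooth muscle and juxtaglomerular cell genes had a median of 0.08 with a list test downwards (adjusted p = 0.897), 2 higher and 2 lower, also adjusted over the list alone, and Tpm2 rose by 2.55 ± 0.58 (adjusted p = 0.00223). Akr1b7 fell by 2.39 ± 0.79 (n = 4 and 4; adjusted p = 0.0217), a call that ended without sieved replicate 1 (adjusted p = 0.062) or 2 (0.0513) or LCM20 replicate 2 (0.0826) or 4 (0.0784), in a range from 0.000869 over its alternatives.

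Oxidative phosphorylation genes were lower in LCM20 as well, with 8 higher and 33 lower of 58, and 9 and 33 adjusted over the list alone. Their median was −0.88 (list test adjusted p = 2.96e-06; adjusted p = 0.383 with an estimated correlation), Atp5mg fell by 4.61 ± 0.24 (n = 4 and 4; adjusted p = 1.25e-08) and Cox4i1 fell by 2.90 ± 0.37 (adjusted p = 2.37e-05). The list was again not matched on sieved level, where random lists matched to the proximal tubule list had a median of −1.01. Ribosomal protein genes did not move as a list, with 9 higher and 11 lower of 34, 10 and 11 adjusted over the list alone, a median of 0.17 and a mean of −0.13 (list test downwards, adjusted p = 0.369). Rps15 fell by 2.47 ± 0.32 (adjusted p = 2.24e-05), Rps24 fell by 2.21 ± 0.23 (adjusted p = 3.70e-06) and Rpl13a rose by 1.99. Cell cycle genes had a median of 0.72 (list test adjusted p = 0.0313; adjusted p = 0.388 with an estimated correlation), with 8 of 18 higher and 11 adjusted over the list alone, and none lower. Top2a rose by 1.18 ± 0.31 (n = 4 and 4; adjusted p = 0.00662), from a signal of 55.3 under the pseudocount, and Mcm4 by 1.12 ± 0.26 (adjusted p = 0.00278). Without LCM20 replicate 1 the cell cycle median was 0.60 and its test did not pass (adjusted p = 0.0886, in a range of 0.0135 to 0.388 over its alternatives). Interferon response genes had a median of 0.76 (list test adjusted p = 0.0244; adjusted p = 0.434 with an estimated correlation), with 10 of 18 higher and none lower, and 10 and 1 adjusted over the list alone. Stat2 rose by 3.69 ± 0.50 (n = 4 and 4; adjusted p = 3.52e-05) and Rsad2, an antiviral gene, by 1.96 ± 0.37 (adjusted p = 0.000512). The other Stat2 probe set changed by 0.82. Lists matched on the sieved level had medians of 0.52 for the cell cycle and 0.36 for the interferon list, and the β-actin 3′ excess was 1.80 ± 0.45 in LCM20 (SD, n = 4).

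The 4 leukocyte genes lower in LCM800 were the 4 lower ones in LCM20 too. RT1-Ba fell by 2.88 ± 0.38 (n = 4 and 4; adjusted p = 2.83e-05), RT1-Bb fell by 2.69 ± 0.30 (adjusted p = 7.78e-06), Cd74 fell by 2.41 ± 0.50 (adjusted p = 0.00109) and RT1-Da fell by 1.98 ± 0.32 (adjusted p = 0.000179), although another RT1-Bb probe set rose by 1.27. The leukocyte list as a whole had 5 higher and 4 lower of 18, also adjusted over the list alone, and a median of −0.02 (list test adjusted p = 0.705). Erythrocyte and platelet genes had 2 higher and 1 lower of 6, also adjusted over the list alone, and a median of 0.53 (list test adjusted p = 0.752). Alas2 rose by 2.03 ± 0.39 (adjusted p = 0.000615), again from a signal under the pseudocount, Slc4a1 fell by 2.32 ± 0.38 (adjusted p = 0.000169) and Hbb changed by 0.88 (adjusted p = 0.262).

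None of the handling and stress lists passed the list test in LCM20. Immediate early and stress genes had 10 higher and 8 lower of 28, 10 and 9 adjusted over the list alone, a median of −0.02, a mean of 0.02 and a list test downwards (adjusted p = 0.752). Rhob fell by 2.40 ± 0.33 (n = 4 and 4; adjusted p = 3.58e-05), Nfkbia fell by 2.71 ± 0.59 (adjusted p = 0.00168) to a signal of 55.0, under the pseudocount, Egr1 rose by 0.81 ± 0.24 (adjusted p = 0.0121) and Fos changed by −0.20 (adjusted p = 0.708). Heat shock genes had 3 higher and 3 lower of 16, also adjusted over the list alone, with a median of −0.01 (list test adjusted p = 0.705), while Hsp90ab1 fell by 3.85 ± 0.48 (adjusted p = 1.90e-05) and Chordc1 rose by 1.61 ± 0.31 (adjusted p = 0.000693). Inflammatory cytokine genes had 5 higher and none lower of 13, also adjusted over the list alone, with a median of 0.58 (list test adjusted p = 0.318) and rises of 1.43 ± 0.23 for Il1b (adjusted p = 0.000165) and 1.16 ± 0.30 for Vcam1 (adjusted p = 0.00499). Hypoxia and glycolysis genes had 7 higher and 7 lower of 22, also adjusted over the list alone, with a median of −0.56 (list test adjusted p = 0.188), while Eno1 fell by 3.72 ± 0.32 (adjusted p = 8.50e-07) and Gpi fell by 2.53 ± 0.35 (adjusted p = 5.04e-05). Iron and oxidative stress genes had 4 higher and 6 lower of 14, also adjusted over the list alone, with a median of −0.37 (list test adjusted p = 0.21). That test passed with the lowest 60% of probe sets left out, at a median of −1.22 (adjusted p = 0.0344), and with no filter (adjusted p = 0.0347), in a range up to 0.683. In the iron list Gclc fell by 3.30 ± 0.45 (adjusted p = 3.52e-05) and Sod2 fell by 1.94 ± 0.37 (adjusted p = 0.000623). Hmox1 rose by 0.72 ± 0.23 (n = 4 and 4; adjusted p = 0.0192), a call that ended without sieved replicate 4 (adjusted p = 0.0707) or LCM20 replicate 3 (adjusted p = 0.064), in a range of 0.0159 to 0.0707 over its alternatives.

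In total 5035 of 11106 probe sets (45.3%) differed between LCM20 and sieved glomeruli, 2908 being higher and 2127 lower, and 3063 of them by a fold of at least 2, 1530 higher and 1533 lower. The sample ranges of 4865 probe sets (43.8%, against 2.86% by chance) did not overlap. Besides Stat2, the largest rises belonged to Lcmt1, Snrpa1, Inf2, Cox7a2l and Aggf1, between 3.22 ± 0.27 for Aggf1 and 3.57 ± 0.30 for Lcmt1 (n = 4 and 4). Besides Atp5mg, the largest falls belonged to Mif, Alpl, Klk1b3, Slco1a6 and Xpnpep2, between −4.82 ± 0.32 for Mif and −4.32 ± 0.34 for Xpnpep2. The LCM20 signals of Mif and Alpl, 47.1 and 25.2, lie under the pseudocount too.

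Both kinds of microdissected glomeruli differed from sieved glomeruli in much the same genes. Among probe sets called in both comparisons, 2453 were higher in both, 1720 lower in both and 2 moved in opposite directions, where independent calls would give 925 and 427. Changes had the same sign for 85.8% of probe sets, and across probe sets, which are not independent replicates, they correlated at r = 0.906. The sieved arrays serve both comparisons, so unchanged groups simulated with shared sieved arrays gave r = 0.530 and 67.7% of equal signs. With the sieved arrays split so that each comparison had its own 2, r was 0.833 to 0.893 over 6 splits.

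Between LCM20 and LCM800, where the question is whether the groups with different numbers in their titles gave the same profile, ribosomal protein genes differed most as a list. Their median was 0.46 higher in LCM20 (quartiles 0.24 and 0.77; list test adjusted p = 3.49e-09; adjusted p = 0.242 with an estimated correlation). No gene of the 34 passed over all genes tested, and 10 passed as higher adjusted over the list alone, the largest being Rpl7 at 1.35 ± 0.38 (n = 4 and 5; adjusted p = 0.111). Oxidative phosphorylation genes were higher by a median of 0.33 (list test adjusted p = 3.23e-06; adjusted p = 0.242 with an estimated correlation), with 0 of 58 past the test over all genes and 1, Ndufs6 (adjusted p = 0.0278), adjusted over the list alone. Genes of the loop of Henle, distal tubule and collecting duct were lower by a median of −0.39 (list test adjusted p = 0.0411; adjusted p = 0.944 with an estimated correlation), with 0 of 21 over all genes and 2, Slc12a3 at −2.05 ± 0.47 and Aqp2 at −1.64 ± 0.41, adjusted over the list alone. Without LCM20 replicate 2 that median was −0.14 and the test did not pass (adjusted p = 0.284), within adjusted p values of 0.00195 to 0.944 over its alternatives. It also failed with the replicate number as a block, at −0.39 (adjusted p = 0.342), and with array weights (adjusted p = 0.366). The same held with 4 times the pseudocount (adjusted p = 0.0777) and with the mean of all probe sets of a gene (adjusted p = 0.0848). In the arrays themselves the ribosomal protein means were 11.37 ± 0.22 in LCM800 (SD, n = 5), 11.87 ± 0.17 in LCM20 and 12.01 ± 0.18 in sieved samples (SD, n = 4 each). The β-actin 3′ excess differed by −0.97 between LCM20 and LCM800 (n = 4 and 5; exact two-sided permutation p = 0.143).

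Few probe sets passed between the microdissected groups, a count that depends on which LCM800 arrays are used. Of 11106 probe sets 17 (0.153%) passed, 8 higher and 9 lower, all by a fold of at least 2, and 1952 had an unadjusted limma p under 0.05. Tra2a, a splicing factor gene, rose by 1.74 ± 0.30 (n = 4 and 5; adjusted p = 0.0289), from 7.56 ± 0.69 to 9.30 ± 0.33 (mean log2 ± SD). The others that rose were Arl3, Senp6, Fam107b, Selenoh and Ufm1, by 1.08 ± 0.18 for Ufm1 to 1.34 ± 0.22 for Arl3. Tspan1 fell by 1.92 ± 0.36 (n = 4 and 5; adjusted p = 0.0413), to a mean signal of 43.9 under the pseudocount. Its change was −3.04 with no pseudocount (adjusted p = 0.0553) and −1.01 with 4 times the pseudocount (adjusted p = 0.0557), and neither passed. Pitpnm2 fell by 1.69 ± 0.28 (adjusted p = 0.0289), and Ly6g6e, Fam193a and Tspyl2 fell, with changes of −1.44, −1.34 and −1.16. These calls rest on few arrays, since leaving out 1 array gave between 0 (without sieved replicate 1, for example) and 502 probe sets (without LCM800 replicate 4). Without LCM800 replicates 4 and 5 there were 2581, with array weights 859, and without LCM800 replicates 1, 2 and 3 there were 23, all higher and 1 of them among the 17. With the replicate number as a block there were 0, with adjusted p values of 0.0708 for Tra2a and Pitpnm2 and 0.0771 for Tspan1, in ranges over all alternatives of 0.000234 to 0.153, 0.000756 to 0.165 and 0.000978 to 0.311. Sample ranges did not overlap for 427 probe sets (3.84%, against 1.59% by chance).

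No marker gene fixed beforehand passed between LCM20 and LCM800, and neither did the podocyte, endothelial or proximal tubule list. Nphs1 changed by 0.11 (adjusted p = 0.899), Synpo by −0.12 (adjusted p = 0.844), Podxl by 0.12 (adjusted p = 0.83), Kdr by 0.74 (adjusted p = 0.298), Thy1 by −0.74 (adjusted p = 0.386), Umod by −0.58 (adjusted p = 0.486) and Slc34a1 by −1.16 (adjusted p = 0.116). Without LCM800 replicate 4 Slc34a1 passed at −1.38 (adjusted p = 0.0311) and Aqp2 at −1.80 (adjusted p = 0.0326). Over the alternatives the adjusted p ran from 0.000674 to 0.752 for Slc34a1, from 0.00595 to 0.491 for Aqp2 and from 0.0431 upwards for Pecam1. List medians were −0.05 for podocyte genes with a list test upwards (adjusted p = 0.987), 0.12 for glomerular endothelial genes (adjusted p = 0.782) and 0.02 for proximal tubule genes (adjusted p = 0.782). The median over all tested probe sets was −0.06 here. Without LCM20 replicate 2 the proximal tubule median was 0.26 and its test passed (adjusted p = 0.0436, the lowest of its alternatives, which ran up to 0.996). Mesangial genes had −0.07 with a test upwards (adjusted p = 0.919), hypoxia and glycolysis genes −0.11 with a test upwards (adjusted p = 0.974), and inflammatory cytokine genes −0.03 with a test upwards (adjusted p = 0.839). Cell cycle and interferon genes had −0.11 (adjusted p = 0.656) and −0.16 (adjusted p = 0.626). Adjusted over the list alone, 1 leukocyte gene, Cd68 at −1.10, and 1 heat shock gene, Dnajb1 at −1.02, passed, and no gene of any list passed over all genes tested. The remaining lists had adjusted p values of 0.558 to 0.987.

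Across probe sets, sieved arrays correlated less with microdissected arrays on average than arrays within any group did with each other. The mean Pearson r per pair was 0.929 within sieved (6 pairs), 0.877 within LCM20 (6 pairs) and 0.824 within LCM800 (10 pairs). Between groups it was 0.817 for LCM800 with LCM20 (20 pairs), 0.598 for sieved with LCM20 (16 pairs) and 0.547 for sieved with LCM800 (20 pairs). Within LCM800, r ran from 0.893 to 0.930 among replicates 1 to 3, was 0.937 between replicates 4 and 5, and ran from 0.718 to 0.812 across these. LCM800 replicates 4 and 5 correlated with LCM20 arrays at 0.855 to 0.907, and replicates 1 to 3 with LCM20 arrays at 0.651 to 0.860. Sieved replicate 3 correlated with the other sieved arrays at 0.873 to 0.897, and these among themselves at 0.964 to 0.984. The deviation of each array from its group mean was 0.508 ± 0.0737 (SD, n = 5) in LCM800, 0.457 ± 0.00821 (SD, n = 4) in LCM20 and 0.327 ± 0.123 (SD, n = 4) in sieved arrays (root mean square, log2). LCM800 and sieved differed in it with an exact two-sided permutation p of 0.0476 (adjusted p = 0.143), LCM20 and sieved with p = 0.143 (exact; adjusted p = 0.175), and LCM20 and LCM800 with p = 0.175 (exact; adjusted p = 0.175). The smallest p these tests allow is 0.0159 for 4 against 5 arrays and 0.0286 for 4 against 4. Deviations within a group share its mean and are not independent, so these p values are approximate as tests of spread.

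**Figure D3:**
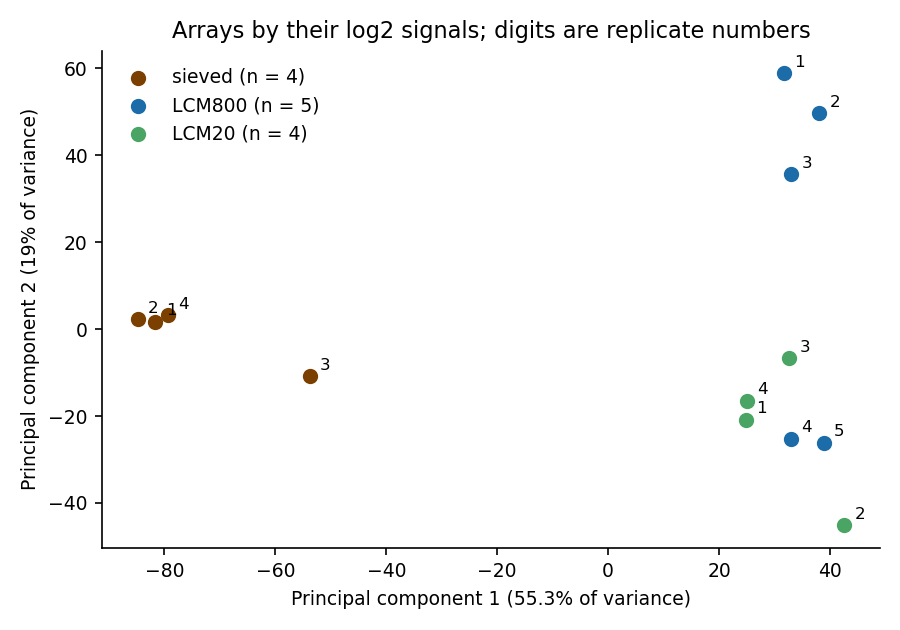
Principal components 1 (55.3% of the variance, x axis) and 2 (19% of the variance, y axis) of the 13 arrays over the tested probe sets, with colours for groups and digits for replicate numbers. Sieved arrays lie apart from both microdissected groups along component 1, and LCM800 replicates 1 to 3 (35.6 to 58.9) lie apart from replicates 4 and 5 (−25.2 and −26.1) along component 2.

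Control probe sets for the ends of 3 transcripts were compared within each array. For β-actin the 3′ signal exceeded the 5′ signal by 0.55 ± 0.02 in sieved (SD, n = 4), 2.77 ± 1.03 in LCM800 (SD, n = 5) and 1.80 ± 0.45 in LCM20 arrays (SD, n = 4). LCM800 differed from sieved by 2.22 (exact two-sided permutation p = 0.0159, adjusted p = 0.0476) and LCM20 from sieved by 1.25 (exact p = 0.0286, adjusted p = 0.0643). For Gapdh the excess was 0.52 ± 0.15 in sieved, 1.22 ± 0.49 in LCM800 (exact p = 0.0159, adjusted p = 0.0476) and 1.14 ± 1.38 in LCM20 arrays (exact p = 0.543, adjusted p = 0.611). LCM20 replicate 4 had a Gapdh excess of 3.06, and without it the difference of LCM20 from sieved went from 0.61 to −0.03. For hexokinase the excess was 0.73 ± 0.14 in sieved and 0.23 ± 0.33 in LCM800 arrays (exact p = 0.0159, adjusted p = 0.0476), on mean signals of only 17.5 to 97.3. All of these but the sieved 3′ signal lie under the pseudocount, so no direction opposite to β-actin is read from them. The hexokinase p, tied with those of β-actin and Gapdh at the smallest value possible, still enters their adjusted p. The mean signal of the β-actin 5′ probe set was 3604 in sieved, 137 in LCM800 and 258 in LCM20 arrays. Signals were lower at the 3′ end too, by log2 changes from sieved to LCM800 of −1.94 for β-actin and −2.70 for Gapdh, against −4.16 and −3.41 at the 5′ end.

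**Figure D4:**
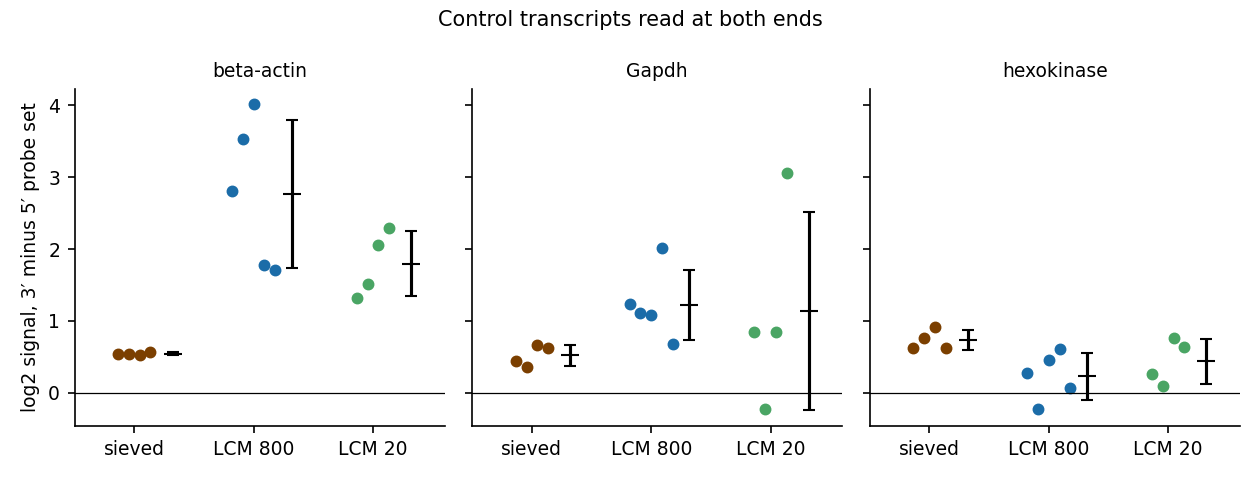
Log2 signal of the 3′ minus the 5′ control probe set for β-actin, Gapdh and hexokinase (y axis) on each array, by group, where points are arrays and bars show the mean ± SD. For β-actin all LCM arrays lie above the sieved arrays, whose mean is 0.55.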

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

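The test of how far the sieved preparations vary in tubule genes was chosen only after the result was seen. A value is listed here when the highest or lowest array of a group lay farther from its nearest neighbour, relative to the range of the group, than Dixon's ratio allows at 95%. This held for 31 of 357 groups of values (8.68%), where chance would give about 1 in 20, and 17 of the 31 lie in sieved replicate 3. All values below are log2(signal + 65.3) unless said otherwise.

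In sieved replicate 3 the proximal tubule list mean was 11.49, against 12.34 to 12.50 in the other sieved arrays, and the mean of the loop, distal tubule and collecting duct list was 9.56, against 10.60 to 10.77. Of genes in these lists, Klk1 was low at 10.87 (others 12.36 to 12.55) and Slc34a1 at 13.25 (13.83 to 13.86). Other genes low in that array, in no tubule list, were Klk1b3, Slco1a6 and Gclc, with 11.46 for Klk1b3 (12.50 to 12.63), 10.64 for Slco1a6 (11.87 to 11.97) and 11.90 for Gclc (12.97 to 13.18). The endothelial genes Egfl7 and Pecam1 were high, at 10.19 (9.00 to 9.03) and 8.82 (8.22 to 8.25). The ribosomal protein list mean was 12.28 (11.90 to 11.93), with Rps24 at 12.32 (11.49 to 11.60). Mad1l1 stood at 7.95 (6.55 to 6.63), Atf3 at 7.37 (6.15 to 6.34), F3 at 9.99 (8.88 to 9.03), Senp6 at 10.38 (9.83 to 9.92) and Fam107b at 11.47 (11.15 to 11.20). The mean Pearson r of this array with its own group was 0.886, against 0.940 to 0.946 for the others.

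Sieved replicate 4 was high in Cd24 at 11.72 (others 11.27 to 11.34) and in Gpi at 11.19 (11.02). In LCM800, replicate 1 was low in Selenoh at 8.73 (9.43 to 9.61), replicate 2 in Sod2 at 6.35 (7.74 to 8.26), replicate 4 in Cox7a2l at 12.50 (13.42 to 13.57) and replicate 5 in Slc4a1 at 8.35 (8.70 to 8.81). In LCM20, replicate 2 was low in Rc3h1 at 10.22 (11.04 to 11.20) and in Slc34a1 at 10.10 (10.89 to 10.95). LCM20 replicate 3 was low in Uqcrfs1 at 9.31 (10.25 to 10.35), F3 at 6.98 (7.78 to 7.84) and Tra2a at 8.81 (9.40 to 9.52), and high in Hmox1 at 9.04 (8.17 to 8.28). LCM20 replicate 4 was high in Mif at 7.75 (6.24 to 6.33) and in Nfkbia at 7.93 (6.20 to 6.47).

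Proximal tubule genes were lower in both microdissected groups, with list medians of −2.98 and −2.75, and sieved replicate 3, the lowest sieved array for both tubule lists, was the highest for the podocyte list at 11.39 and the endothelial list at 10.36. Signal lost in amplification for any transcript of this abundance is argued against, since random lists matched on sieved level had medians of −1.24 and −1.01, and the list lay at percentile 0 of 10000 such lists in both comparisons. Tubule RNA in the sieved preparations stays a candidate explanation: the list mean varied over the sieved arrays with an SD of 0.478, at percentile 100 of matched lists (0.0450 to 0.256), but most of that SD rests on replicate 3, whose low value was known before this test, and without it the SD was 0.0829 at percentile 98.7 (0.00579 to 0.0770). A list of genes regulated together may also vary more than a random one, and the labels give a purity over 99% by microscopy. Tubule genes were also read in the microdissected arrays, with LCM800 mean signals of 4064 for Slc34a1, 2350 for Umod and 9584 for Aqp2. In sieved arrays these were 13434.5, 14085 and 4278, so of these only Aqp2 was higher in LCM800, and in LCM20 it was at 3158. Tubule RNA in sieved samples alone would not give the higher Aqp2 of LCM800. No biological explanation was tested, since every sample is from untreated glomeruli, and effects of perfusion or clamping remain open because each went with one preparation.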

How the results depend on the processing

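Leaving out LCM800 replicates 4 and 5 or replicates 1, 2 and 3 and the spike-in covariate were tests chosen only after the result was seen, and the cause of a change below was not tested unless stated. No change of a named gene or list that passed with the main processing changed direction in an alternative. For changes that did not pass there, direction was not tracked. The count between LCM20 and LCM800, 17 probe sets, was the least stable: it was 10 with no pseudocount, 10 with no filter, 0 with only the 2 groups in the fit, 11 with 1 probe set per gene, 859 with array weights, 0 with the spike-in covariate and 2581 without LCM800 replicates 4 and 5. Leaving out 1 array gave 0 (without sieved replicate 1, for example) to 502 (without LCM800 replicate 4). With the replicate number as a block it was 0, beside 5452 and 4874 probe sets for LCM800 and LCM20 against sieved, and the correlation of the comparisons was 0.873 in place of 0.906. The pairing that such a block needs was not seen in the values: after group means were removed, same-number pairs from different groups correlated at −0.24 to 0.23 over 12 pairs. With the lowest 60% of probe sets left out the counts against sieved were 3504 and 3259, and with a fold of at least 2 they were 3223 and 3063, which follows from counting fewer. With an estimated correlation 0 lists passed in each comparison, against 6, 5 and 3. Without LCM800 replicates 4 and 5 only 1 list passed between LCM20 and LCM800, and the correlation of the comparisons was 0.804. Leaving out 1 array gave correlations of 0.872 to 0.927. The mean r of array pairs moved with the filter: within LCM20 it was 0.923 with no filter and 0.835 with the lowest 60% left out, for sieved with LCM800 0.737 and 0.334, for sieved with LCM20 0.764 and 0.406, and for LCM800 with LCM20 0.740 with the lowest 60% left out. Within LCM20 it was 0.852 with no pseudocount and 0.893 with 4 times the pseudocount, and within LCM800 it was 0.937 without replicates 1, 2 and 3. The 3′ excess of LCM800 over sieved with no pseudocount was 2.72 for β-actin (exact permutation, adjusted p = 0.0714), 0.85 for Gapdh (adjusted p = 0.0714) and −0.55 for hexokinase (adjusted p = 0.796). With 4 times the pseudocount these were 1.47 (exact permutation, adjusted p = 0.0714), 0.43 (adjusted p = 0.103) and −0.21 (adjusted p = 0.0714). With the pseudocount used above all 3 controls had the smallest exact permutation p possible, 0.0159. At that limit an adjusted p depends on how many of the 9 tests reach it, hexokinase included, and not on the β-actin values alone. Without LCM800 replicates 1, 2 and 3 the β-actin difference was 1.20 against sieved (exact permutation, adjusted p = 0.3) and 0.051 for LCM20 against LCM800. With so few LCM800 arrays the test against sieved could not pass whatever the values. The 2 arrays left had 1.78 and 1.71, above the 0.53 to 0.57 of the sieved arrays. The difference in spread between LCM800 and sieved was 0.0344 without LCM800 replicates 4 and 5, −0.0141 without replicates 1, 2 and 3, and 0.132 to 0.291 with 1 array left out. Between LCM20 and sieved it was 0.0812 to 0.240 with 1 array left out, and between LCM20 and LCM800 it was 0.0957 without LCM800 replicates 4 and 5 and 0.144 without replicates 1, 2 and 3. Among changes of named genes with 1 array left out, 835 values for LCM800 against sieved kept their call, 1 gained and 9 lost it; 811, 2 and 6 did so for LCM20 against sieved, and 243, 2 and 93 for LCM20 against LCM800. With other settings these were 749, 4 and 9, then 737, 0 and 0, then 253, 5 and 46. For list medians they were 254, 6 and 0, then 258, 1 and 1, then 255, 1 and 4 with 1 array left out, and 261, 10 and 7, then 270, 3 and 5, then 268, 0 and 10 with other settings.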

Other observations

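Among the tests in this part, leaving out LCM800 arrays, the spike-in covariate and the separate reading of the cell cycle and interferon lists were chosen only after the result was seen. Genes of the extracellular matrix changed one by one and not as a list. In LCM800 against sieved 6 rose and 5 fell of 31, also adjusted over the list alone, with a median of 0.05, a mean of 0.11 and a list test downwards (adjusted p = 0.849). In LCM20 6 rose and 5 fell, 5 and 5 adjusted over the list alone, with a median of −0.05 (list test adjusted p = 0.676). Lamb2, which encodes the laminin chain of the mature glomerular basement membrane, rose by 2.38 ± 0.30 in LCM800 (n = 5 and 4; adjusted p = 1.36e-05) and by 2.17 ± 0.32 in LCM20 (n = 4 and 4; adjusted p = 6.62e-05). The proteoglycan gene Dcn fell by 2.35 ± 0.30 (adjusted p = 1.82e-05) in LCM800 and fell by 2.65 ± 0.32 (adjusted p = 1.42e-05) in LCM20. Of 16 complement and coagulation genes 3 rose and 7 fell in LCM800 (median −0.20; list test adjusted p = 0.0701), and 5 rose and 7 fell in LCM20 (median −0.21; list test adjusted p = 0.21), both also adjusted over the list alone. The LCM800 test of this list passed without sieved replicate 2 (adjusted p = 0.042), sieved replicate 4 (0.0428), LCM800 replicate 4 (0.0447) or LCM800 replicate 5 (0.0479), in a range of 0.0241 to 0.494 over its alternatives. Its median moved to −0.51 with the mean of all probe sets of a gene (adjusted p = 0.0328), to −0.43 without LCM800 replicates 4 and 5 (adjusted p = 0.0241) and to −0.32 with array weights (adjusted p = 0.0446), and it passed in each. Plau, the urokinase gene, fell by 3.17 ± 0.37 (adjusted p = 7.28e-06) and fell by 3.25 ± 0.39 (adjusted p = 1.32e-05) in LCM800 and LCM20, F3, the tissue factor gene, fell by 1.87 ± 0.30 in LCM800 (adjusted p = 0.000106), and Tfpi rose by 1.99 ± 0.52 in LCM20 (adjusted p = 0.00632) while another Tfpi probe set changed by −1.22.

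Probe sets of the same gene were often called in opposite directions. In LCM800 against sieved this held for 90 of 314 genes with several called probe sets (28.7%, against 52.3% when probe sets were shuffled), and in LCM20 for 89 of 260 (34.2%, against 51.4%). In 50 genes it held in both comparisons. Examples chosen after their values were seen, from LCM20 against sieved, are Canx with 1.18 and −3.80, Ccnd1 with 0.88 and −3.43 and Jun with 2.10 and −1.61. A single probe set therefore does not always stand for its gene here, and probe set positions along the transcript were not used.

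Other splits of the samples ask whether groups of arrays put together at random give as many calls. For LCM800 against sieved 1 of 100 splits drawn from 126, the real one with 5764 probe sets, gave as many, the highest other giving 3914, so chance is unlikely. For LCM20 against sieved it was 1 of 35 splits, with 5035 against at most 1, so chance is unlikely. The smallest share that 35 splits allow is 2.86%. Preparation and amplification go with these groups, so the splits tell only that the groups differ. Between LCM20 and LCM800 9 of 100 splits drawn from 126 gave at least the 17 probe sets of the real one, so chance is not excluded. The highest of these gave 2106 and put LCM800 replicates 1, 2 and 3 with LCM20 replicate 3, which points to a structure of the samples other than their groups.

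Ribosomal protein and oxidative phosphorylation genes were higher in LCM20 than in LCM800, with medians of 0.46 and 0.33. Covariates from control probe sets did not lower these medians: with the β-actin 3′ value the lower of them, in percent of its value, was 129%, and with the spike-in level it was 103%. Both covariates also separate LCM800 replicates 1 to 3 from replicates 4 and 5. The β-actin value was 2.80 to 4.01 against 1.78 and 1.71, and the spike-in level 10.06 to 10.63 against 8.97 and 9.79. Because the covariates go with that structure, these fits do not decide whether either reading plays a part. LCM800 arrays that stand apart are argued against as the whole cause, as the lowest median was 80.0% of its value, yet without LCM800 replicates 4 and 5 the oxidative phosphorylation call ended. There its median went from 0.33 (quartiles −0.05 and 0.59) to 0.29 (quartiles −0.43 and 0.77; adjusted p = 0.0641), with fewer arrays and an SD of changes over all genes that went from 0.454 to 0.687, against which the list is tested. No biological explanation was tested, what the title numbers stand for goes with the groups, and with an estimated correlation neither list passed (adjusted p = 0.242 for both).

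Cell cycle and interferon genes were higher in both microdissected groups, by medians of 0.79 and 0.72 and of 0.84 and 0.76. Many probe sets that are dim in the sieved arrays rose, and before the result was seen the test asked both lists together to rise beyond matched lists, which the cell cycle list did not, so as first written the test leaves this explanation open for the whole pattern. Read list by list afterwards, the interferon medians lay at percentiles 98.3 and 98.9 of 10000 random lists matched on sieved level, the lower being 98.25. The list thus rose further than most matched lists. Genes regulated together may vary more than a random list, the estimated correlation of this list was 0.168, and both comparisons share the sieved arrays. These percentiles therefore do not decide whether a rise of dim probe sets accounts for the interferon list. The cell cycle medians lay at percentiles 83.9 and 92.9 of lists matched on sieved level, so a rise of dim probe sets may account for that list. Among random lists matched on mean log2 over all arrays they lay at percentiles 99.79 and 99.96. That reading therefore depends on the matching and stays open. No biological explanation was tested, as the design holds no group of proliferating or interferon-treated glomeruli.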
